A study of Mus musculus with 4 samples.

How the data were processed

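Cells were washed from the airspaces of C57BL/6 mice by bronchoalveolar lavage, which samples the cells lying free in the alveoli and airways. Per the labels, 4 groups were studied. They had breathed either filtered air or an aerosol of Afghanistan particulate matter (APM), a mineral dust given in whole-body chambers at 5 mg/m3 for 6 hours a day on 12 days. Starting 9 days after the last APM exposure, they received house dust mite (HDM), an allergen used to induce allergic airway inflammation, or saline through the nose. The HDM dose was 10 µg, with sensitization on days 22 and 29, challenge on days 36, 37 and 38 and harvest on day 39. Lavage cells of 7 mice were pooled into 1 library per group, so the study holds 4 libraries: control, HDM, APM and HDM+APM. The cells passed 70 µm and 40 µm strainers, and 60 to 80% of them were viable by dye exclusion, per the labels.

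Libraries were made with the 10x Genomics 3' v2 kit, which tags each captured transcript with a unique molecular identifier (UMI) so that amplified copies are counted once. The submitters' processing notes name Cell Ranger 2.2.0, Seurat 2.3.4 and the mouse build mm10, without saying which step each served. The authors deposited UMI counts, not normalized, in 1 matrix of 13838 genes by 9925 cells with 33643423 UMIs in all. A metadata table deposited with it gives each cell's library, 1 of 7 coarse cell types and 1 of 17 refined clusters. No deposited cell held under 496 or over 9998 UMIs, under 253 genes, or over 9.99% mitochondrial UMIs. Which filters produced those limits is not given in the sources used here, and all cells were kept as deposited. Immunoglobulin constant region genes such as Ighm and Iglc2 were not analysed here.

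Depth differed between libraries. The control, HDM, APM and HDM+APM libraries held 15170333, 1920648, 11355310 and 5197132 UMIs, and their median UMIs per cell were 3417, 1380, 2637 and 4780. Cells under 1000 UMIs made up 1.25, 29.4, 4.09 and 5.88% of them. A class of cells entered a comparison only with at least 50 cells in both libraries.

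The cell types, the gene lists, the comparisons and the rule for naming genes were fixed before the data were examined. Cell types were taken from the deposited annotation and checked against 19 marker lists by the 10 genes with the highest fold in each cluster over all other cells. Macrophage 8, a cluster the authors placed among the alveolar macrophages, held 2 monocyte-derived macrophage markers and no alveolar macrophage marker among its 10 leading genes. Alveolar macrophages were therefore compared by cluster number, as Macrophage 8 and as Macrophages 1 to 7, 9 and 10 together, a departure from the planned single class made after the data were seen. The single class was kept as an alternative. The type named epithelial had 4 red blood cell and 3 epithelial markers among its leading genes, and its expression was not compared between libraries. Its levels are given only beside genes of other classes. The type named classical monocyte had 3 monocyte-derived macrophage markers and no monocyte marker there, so its cells are called the cells the authors named classical monocyte. In 23 cells the coarse type was epithelial while the refined cluster was a macrophage one. Those cells count as epithelial in the coarse shares and enter no macrophage sum.

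UMIs were summed over the cells of a class in a library and scaled by that sum to CPM, counts relative to a fixed total shared by all libraries. A ratio of CPM is given with its exact conditional binomial 95% interval, a CPM with an exact Poisson interval and a share of cells with an exact (Clopper-Pearson) binomial interval. All of these cover counting error only. Log2 ratios used a pseudocount of 10 CPM, which understates the ratio of low genes. Where a gene had 0 UMIs in a library, its ratio is a lower bound against 3 counts over that library's class. Each of 23 gene lists was summarised by the median log2 ratio of its members with at least 20 UMIs over both libraries, and lists with under 5 such members are called not measured. The list's percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries and tests nothing. Members are counted as higher or lower where the interval of their own ratio excluded 1. The counting range of a median came from redrawing the counts.

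The design implied 4 comparisons: HDM with control, APM with control, HDM+APM with HDM and HDM+APM with APM. With 1 pooled library per group there are no replicates, so no test between groups was made and no p-value is given. The named genes are, per class and comparison, the 6 with the highest and the 6 with the lowest log2 ratio among genes of at least 50 CPM in either library and at least 50 UMIs over both, plus up to 4 members of a fixed list with the largest absolute log2 ratio. The second class under that rule was T cells in both HDM+APM comparisons, with more cells than B cells against HDM. Against control, no class outside the alveolar macrophages had 50 cells in both libraries. Genes that lead Macrophage 8 are not given as its results. Macrophages 1 to 7, 9 and 10 are a sum over 9 clusters, so several genes named for the sum lead 1 of them, which is said beside them.

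The ratio intervals and list percentiles were tested on counts simulated from a profile pooled over the libraries compared. Counts were drawn independently, as the intervals assume, with no variation between cells, mice or libraries. The rates below therefore cover counting error only. For Macrophage 8, HDM over control, 1721 genes were simulated. The interval excluded 1 on the right side for 86% of genes set to a ratio of 2 and 100% of those set to 4, and for 68% and 100% at ratios of 0.5 and 0.25, and it held the true ratio for 95.9% of unchanged genes. For Macrophages 1 to 7, 9 and 10, HDM over control, 9249 genes gave 48% and 94% for the higher ratios, 26% and 50% for the lower ones and 97.3% for unchanged genes. Lower genes are therefore missed more often there, and counts of 0 or few lower members in that comparison are a weak statement. For APM over control, 9916 genes gave 100% and 100%, 94% and 100%, and 95.6%.

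Alternatives changed 1 choice at a time: pseudocounts of 1 and 50 CPM, TMM factors from edgeR 4.0.16 under R 4.3.3, a total without mitochondrial, ribosomal protein, haemoglobin and the 20 most abundant genes, the mean over cells, cells thinned to 1000 UMIs, free RNA at 5% of a class subtracted, list minimums of 100 UMIs or none, lists without the genes that lead a cluster of the class, cluster shares made equal for APM over control in Macrophages 1 to 7, 9 and 10 (CPM per cluster with at least 20 cells in both libraries, weighted by its UMIs over both), and shares over cells of at least 1000 UMIs or 500 genes. Own clustering in scanpy 1.11.5 used 2000 variable genes, 30 components and Leiden resolution 1. Scrublet marked 5 of the 9925 cells as doublets, too few to have worked, so doublets were kept as deposited. Other steps ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Gene positions are from the GENCODE vM21 annotation of mm10.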

Results

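Single-cell transcriptomes were recorded from lavage cells of mice that had breathed filtered air or APM dust and were then given saline or HDM allergen. The study holds 4 groups with 1 library each, and each library pools 7 mice. The control library gave 3918 cells, the HDM library 994, the APM library 3890 and the HDM+APM library 1123. They held 15170333, 1920648, 11355310 and 5197132 UMIs. Median depth was lowest in the HDM library, at 1380 UMIs and 608.5 genes per cell, and highest in the HDM+APM library, at 4780 UMIs per cell. Because each group is a single pooled library, no difference below has a replicate check and p-values are absent. All intervals are 95% intervals for counting error only, and each difference describes these libraries.

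The first question is which cells each exposure left in the airspaces. Cells the authors named alveolar macrophage, the resident phagocyte of the alveoli, made up 99.1% of control cells (98.7 to 99.4) and 95.04% of APM cells (94.3 to 95.7). They were 20.02% of HDM cells (17.6 to 22.6) and 13.8% of HDM+APM cells (11.8 to 16.0). Of these 199 HDM and 155 HDM+APM cells, 139 and 109 belonged to Macrophage 8, which had no alveolar macrophage marker among its leading genes. The other macrophage clusters held 60 and 46 cells. T cells were the largest type of the HDM library, at 49.6% (46.4 to 52.8), against 0.332% in control (0.177 to 0.567), 1.34% in APM and 12.1% in HDM+APM (10.3 to 14.2). B cells made up 12.9% of HDM cells (10.9 to 15.1) and 40.0% of HDM+APM cells (37.1 to 42.9). The control library held 0 B cells of 3918, which allows a share of up to 0.0766%, and the APM library held 3.

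Granulocyte-like cells, led by the neutrophil markers S100a8, S100a9 and G0s2, formed 13.3% of the HDM library (11.2 to 15.5), 3.47% of HDM+APM (2.48 to 4.72), 0.746% of APM and 0.179% of control. These cells were shallow, with medians of 647.5 UMIs in HDM and 811 in HDM+APM. Their HDM share was 0.285% when only cells with at least 1000 UMIs were counted. The difference between HDM and HDM+APM is therefore stated for all deposited cells only. Dendritic cells, which carry antigen to lymph nodes, formed 3.82% of HDM cells (2.72 to 5.21) and 0.890% of HDM+APM cells (0.428 to 1.63). Shares within a library sum to 100%, so a large type lowers all the others. Among cells other than alveolar macrophages, T cells were 62.0% in HDM and 14.0% in HDM+APM (11.9 to 16.4), and B cells were 16.1% and 46.4% (43.2 to 49.6). Of the 449 HDM+APM B cells, 404 belonged to the cluster named B cells 2, which held 9 cells in HDM and 0 in APM. A cluster lying mostly in 1 library may be that library rather than a cell type.

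**Figure D1:**
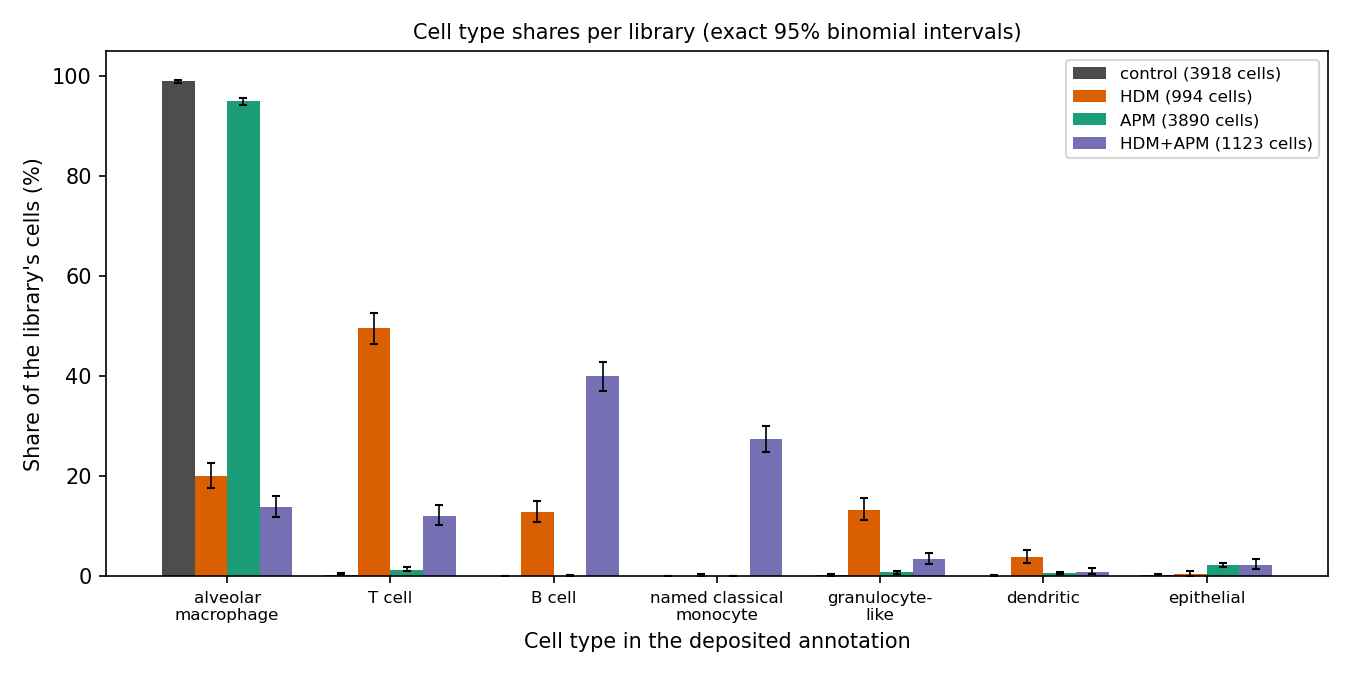
Bars give the share of each library's cells in the 7 deposited cell types, in percent, with exact 95% binomial intervals as black lines. Alveolar macrophages fill 99.1% of the control and 95.04% of the APM library, while T cells (49.6%) lead the HDM library and B cells (40.0%) the HDM+APM library.

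The series title singles out a monocyte population in the combined exposure. The cells the authors named classical monocyte numbered 308, all in the HDM+APM library, where they were 27.4% of cells (24.8 to 30.1) and 31.8% of the cells other than alveolar macrophages. The control, HDM and APM libraries held none, which allows shares of up to 0.0766, 0.302 and 0.0771%. Their leading genes were Retnla, an alternative activation gene of macrophages, Prg4, Alox15, Saa3, the complement genes C1qb, C1qc and C4b, Fn1, Pf4 and Cd5l. Of the 14 monocyte markers fixed before the data were examined, 3 had their highest level in these cells: F13a1 at 35.4 CPM, Ifitm6 at 167 CPM and Vcan at 4.27 CPM. Ly6c2, a surface marker of inflammatory monocytes, stood at 10.4 CPM (6.04 to 16.6) against 535 CPM in T cells, and Ccr2, their chemokine receptor, at 5.49 CPM (2.51 to 10.4) against 124 CPM in T cells. Of 18 monocyte-derived or interstitial macrophage markers, 10 were highest in these cells, among them Csf1r at 427.5 CPM. Of 17 alveolar macrophage markers 1 was, Chil3 at 11250 CPM.

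Macrophages of the pleural and peritoneal cavities carry a transcription programme set by Gata6. These cells held Gata6, named here after its value was seen, at 136 CPM (119 to 155) and Prg4, which encodes the lubricant lubricin, at 1762 CPM (1698 to 1827). A list of 12 further cavity macrophage genes, written down before their values were looked at, was highest in these cells for all 12, with the other types taken over the 4 libraries, although the interval of Hgf, at 5.49 CPM (2.51 to 10.4), took in the 2.69 CPM of alveolar macrophages. Within the HDM+APM library Car6 was at 24.4 CPM in them and 28.5 CPM, on 1 UMI, in granulocyte-like cells. Its most abundant members were Serpinb2 at 402 CPM, Ltbp1 at 309 CPM and Fcna at 253 CPM. In GENCODE vM21 on mm10, Gata6 lies on chromosome 18 at 11052064 to 11085635, Prg4 on chromosome 1 at 150449412 to 150466165, Ly6c2 on chromosome 15 at 75108158 to 75111970 and Ccr2 on chromosome 9 at 124101950 to 124113557. All 4 are protein-coding.

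**Figure D2:**
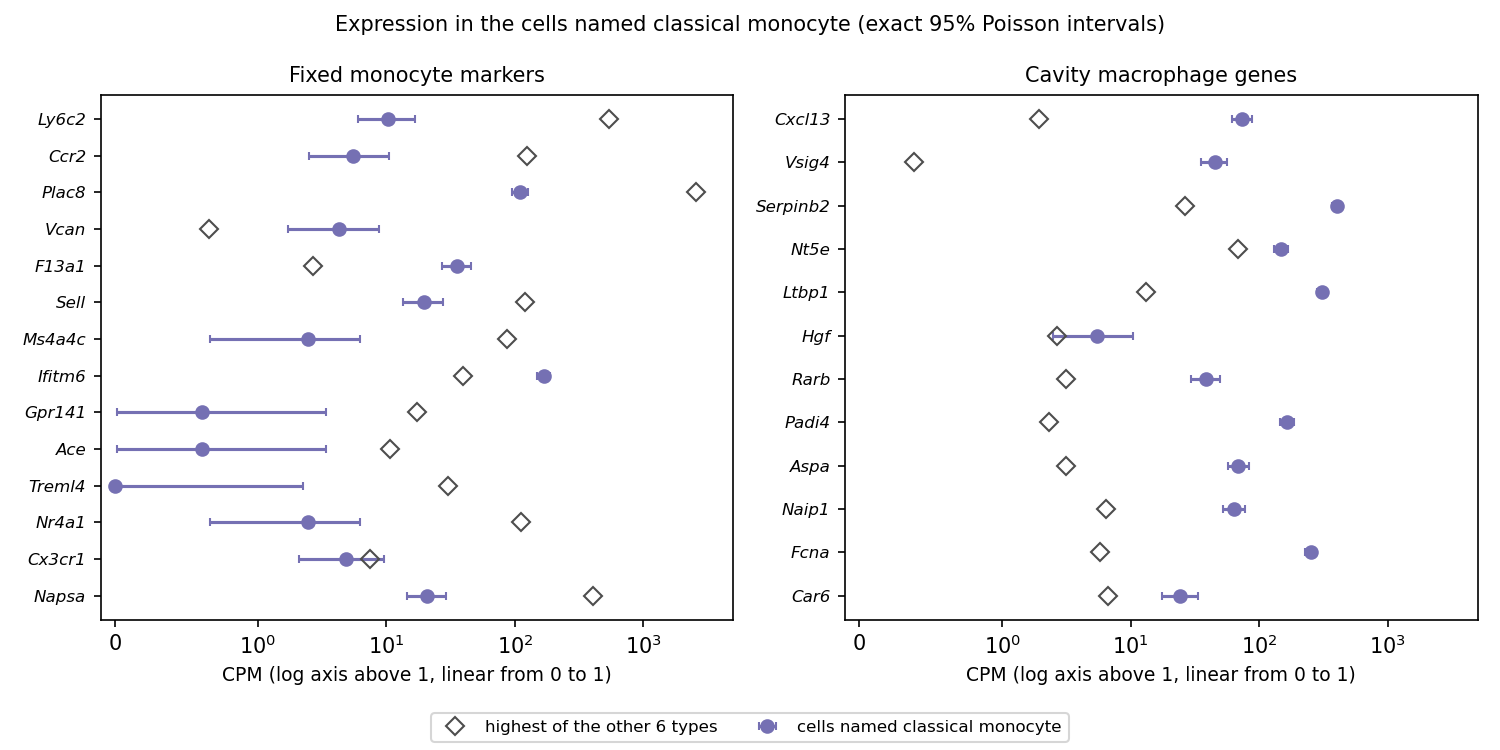
Points give CPM in the 308 cells named classical monocyte with exact 95% Poisson intervals, and open diamonds the highest CPM among the other 6 types over the 4 libraries, on an axis that is linear from 0 to 1 and logarithmic above. Among the 14 fixed monocyte markers on the left 3 points lie to the right of their diamond, and among the 12 cavity macrophage genes on the right all 12 do.

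HDM was compared with control to ask how airspace macrophages differed with the allergen alone. Macrophage 8 was 2.76% of control and 69.8% of HDM alveolar macrophages, with 107 and 139 cells. Their median depths were 1167 and 3056 UMIs. Whether the same kind of cell carries that name in both libraries was not tested. Ratios within it may therefore reflect different cells as well as changed expression. In Macrophage 8, genes of alternative activation, the state macrophages enter under interleukin 4 and 13, were higher in the HDM library. Of 18 measured members 11 were higher and 0 lower, with a median log2 ratio of 1.64 (1.45 to 2.09). Ccl8, a chemokine for T helper 2 cells, was at 298 CPM against 0 UMIs in control, at least 14.0-fold higher, and Retnla at 213 CPM against 0, at least 9.99-fold higher. CC and CXC chemokines had a median of 1.93 (1.79 to 2.49), with 10 of 16 higher and 0 lower. Ccl5, which attracts T cells, was 35.2-fold higher (6.19 to 1401) on 1 control UMI, and Cxcl3, a neutrophil attractant, at least 5.81-fold higher. T cells of the HDM library held Ccl5 at 4804 CPM, and Macrophage 8 at 250.4 CPM. Retnla was at 248 CPM in granulocyte-like cells of that library, 81.9 in T cells, 72.3 in B cells and 63.6 in dendritic cells. With 5% free RNA subtracted its log2 ratio in Macrophage 8, 4.49, stayed within its interval. That step takes off 5% of the library's mean level, less than these other types held. It cannot decide whether free RNA plays a part. Arg1, Ccl17, Ccl24, Mmp12, Rnase2a and Ccl9 lead this cluster and are not given as its results. Arg1, Ccl17 and Ccl24 count in the alternative activation list, and Ccl9, Ccl17 and Ccl24 in the chemokine list. Both medians lay above all 10000 matched random lists. Without genes that lead the cluster they were 1.08 and 1.85, and over the other settings they reached 2.67 and 3.03 in cells thinned to 1000 UMIs. With no minimum of UMIs the chemokine median was 1.08.

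Interferon response genes were also higher in Macrophage 8 of the HDM library, with 11 of 13 higher, 0 lower and a median of 2.33 (1.66 to 2.64). With 4 members at 0 UMIs in control set to their bound, that median was 1.54, and with a pseudocount of 50 CPM it was 1.09. Gbp2, a guanylate-binding protein, was at least 4.59-fold higher and the antiviral gene Ifitm3 7.60-fold higher (3.61 to 19.2), a gene at 1444 CPM in granulocyte-like cells. MHC class I genes, which display peptides to CD8 T cells, had a median of 1.04 (0.71 to 1.41) with 5 of 10 higher and 0 lower. Examples are H2-K1 at 2915 against 954 CPM, a ratio of 3.06 (2.56 to 3.68), and H2-T23 at 7.03 (2.93 to 22.1). Unfolded protein response genes had 6 of 11 higher and 0 lower, led by Sdf2l1 at 4.85-fold (2.28 to 12.3) and the chaperone Hspa5 at 2.84-fold (2.16 to 3.79). Among classical monocyte genes 6 of 10 were higher and 1 lower, with Plac8 at least 4.18-fold and Ly6c2 at least 3.36-fold higher. Lymphocytes of the HDM library hold both, Plac8 at 2093 CPM in B cells and Ly6c2 at 549 CPM in T cells, against 89.3 and 71.9 CPM in Macrophage 8. Lysosomal genes had 12 of 23 higher and 4 lower, with the protease Lgmn 4.32-fold higher (3.08 to 6.24), and matrix remodelling genes had 8 of 15 higher and 2 lower.

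Oxidative stress response genes under the transcription factor Nrf2 were lower in Macrophage 8 of the HDM library. Of 17 measured, 15 were lower and 1 higher, with a median of -1.22 (-1.42 to -1.05), below all random lists. Hmox1, the haem-degrading enzyme, was at 270.0 against 1374 CPM, 5.09-fold lower (4.04 to 6.43), Blvrb, the next enzyme of haem breakdown, 7.38-fold lower (4.77 to 11.7) and Gclm, of glutathione synthesis, 5.11-fold lower (2.62 to 10.2). The metallothioneins Mt1 and Mt2, which bind zinc and copper, were 7.56-fold (6.82 to 8.38) and 11.1-fold (9.12 to 13.6) lower. All cells named alveolar macrophage held Mt1 at 14041 CPM and the Nrf2 target Prdx1 at 6161 CPM in control. They were 99.1% of control and 20.02% of HDM cells. What their free RNA adds to Macrophage 8 was not tested. Hspa1a, an inducible heat shock protein, was 66.5-fold lower (34.3 to 148) and Gstm1, a glutathione transferase, 14.2-fold lower (9.26 to 22.4). The heat shock and dissociation list had 9 of 19 lower, 2 higher and a median of -0.50, which was 0.23 when all cells named alveolar macrophage were taken as 1 class. Gm26917 was 11.1-fold lower (9.22 to 13.5), a log2 ratio of -3.44 that was 0.68 in that single class. Hbb-bt, a haemoglobin transcript of red blood cells, was 56.6-fold higher (10.0 to 2247) on 1 control UMI, and mitochondrial transcripts had a median of 0.36 with 10 of 12 higher.

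In Macrophages 1 to 7, 9 and 10, of which the HDM library held 60 cells and control 3775, the medians of the alternative activation, chemokine, interferon, MHC class I and Nrf2 lists had the same signs as in Macrophage 8. Alternative activation had 11 of 14 higher, 0 lower and a median of 1.21 (0.96 to 1.48). Ccl17, a chemokine that recruits T helper 2 cells, was at 743 against 12.3 CPM, 60.3-fold higher (49.0 to 74.2), and Chil3, a chitinase-like protein, 4.63-fold higher (4.52 to 4.73). The matrix protease Mmp12 was 36.0-fold higher (28.0 to 46.2), AA467197 28.3-fold (22.3 to 35.8), Ccl5 34.1-fold (22.3 to 51.5) and Ccl4 20.96-fold (13.8 to 31.2). Dendritic cells of that library held Ccl17 at 6598 and AA467197 at 2213 CPM, T cells Ccl5 at 4804 CPM and granulocyte-like cells Ccl4 at 27549 CPM, and with 5% free RNA subtracted the log2 ratios of Ccl5 and Ccl4 went from 3.47 to 1.92 and from 3.13 to 2.11. Under the same subtraction the log2 ratios of Mmp12 and AA467197 also left their intervals, at 4.24 and 4.06. Ccl17, Mmp12 and AA467197 are leading genes of Macrophage 8, which held 139 of the HDM library's 199 alveolar macrophages. Their ratios here are therefore no independent sign of a change in these clusters. Nrf2 targets had 16 of 20 lower, 0 higher and a median of -0.76 (-0.996 to -0.67). Hmox1 was 2.99-fold lower (2.60 to 3.46), Slc7a11, the cystine importer, 3.08-fold lower (2.13 to 4.64), Mt1 3.07-fold lower and Mt2 3.30-fold lower (2.96 to 3.68). These 4 genes lead cluster 2, which held 7 of the 60 HDM and 566 of the 3775 control cells, and Slc7a11 also leads cluster 3, with 9 and 906 cells. The values therefore combine cluster shares with expression. Without the genes that lead a cluster the Nrf2 median was -0.64, and alternative activation had 0.64 with a pseudocount of 50 CPM.

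Cell cycle genes were higher in these clusters, 15 of 22 with 1 lower and a median of 0.83 (0.64 to 1.04). Rrm2, of DNA synthesis, was 4.83-fold higher (3.35 to 6.76) and Top2a, the DNA topoisomerase, 3.32-fold (2.40 to 4.49). Both lead the proliferating cluster 7, which held 12 of the 60 HDM cells and 241 of the 3775 control cells. The median was 0.78 without genes that lead a cluster and 0.10 with all alveolar macrophages as 1 class, 9 of 22 higher and 2 lower. The interferon list had 11 of 18 higher, 0 lower and a median of 0.85, MHC class I had 9 of 11 higher and a median of 0.76 (0.58 to 1.06), and chemokines had 7 of 17 higher and a median of 0.54. In cells thinned to 1000 UMIs the interferon and chemokine medians were -0.01 and -0.02. Clec4d, a lectin receptor, was 4.36-fold lower (2.37 to 9.10) and Ptgr1 13.9-fold lower (2.49 to 549.8) on 1 HDM UMI. Hbb-bt was 11.7-fold higher (8.61 to 15.6).

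**Figure D3:**
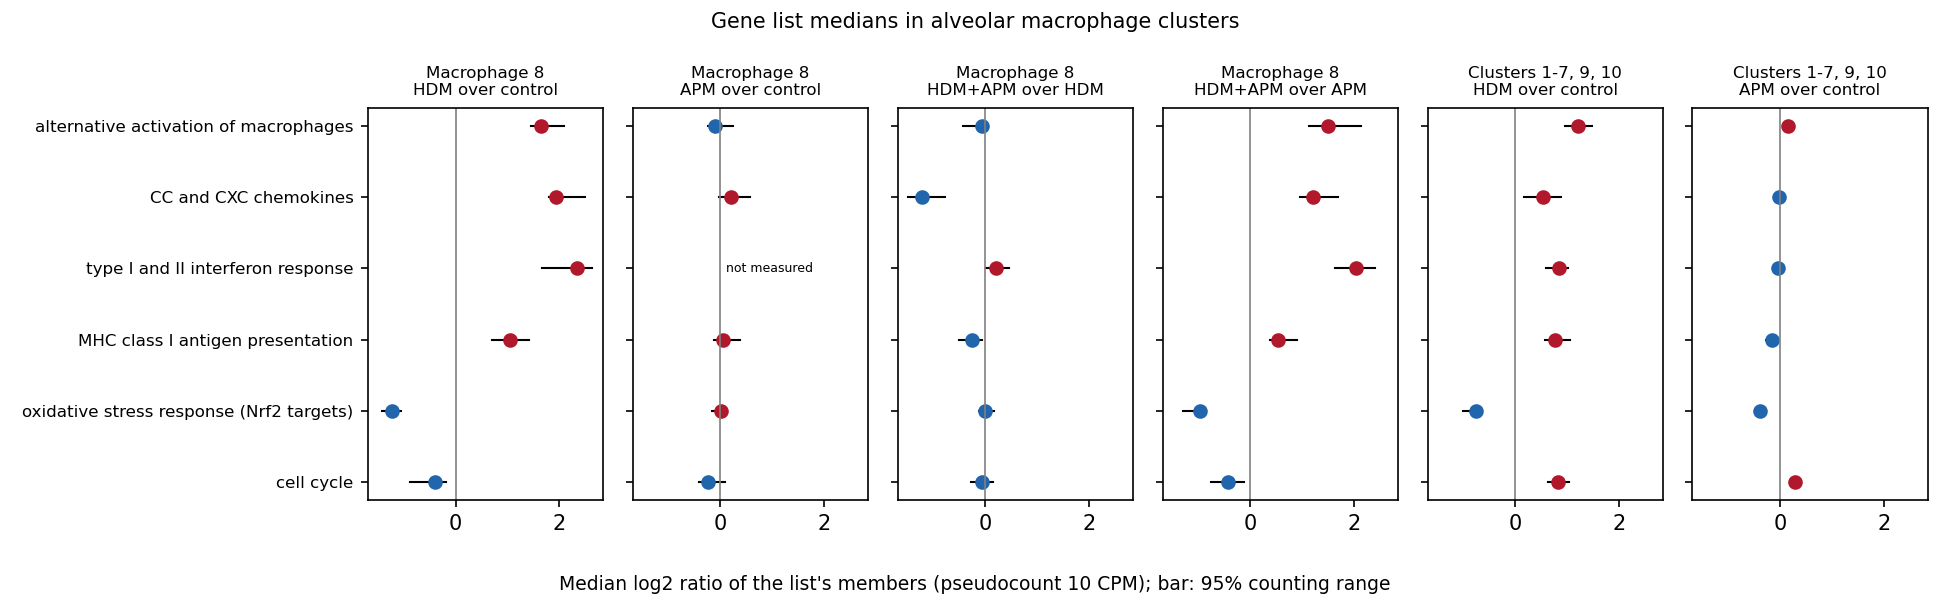
Each panel gives the median log2 ratio of 6 gene lists in 1 macrophage class and comparison, with the 95% counting range as a line, red above 0 and blue below. Nrf2 target medians lie at -1.22 and -0.76 for HDM over control and at -0.39 for APM over control in Macrophages 1 to 7, 9 and 10 (-0.05 with cluster shares made equal), and the chemokine median lies at -1.23 for HDM+APM over HDM in Macrophage 8, or between -1.59 and -0.56 over the other settings.

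APM was compared with control to ask what the dust alone left behind in the macrophages weeks after exposure. In Macrophages 1 to 7, 9 and 10, with 3492 APM and 3775 control cells, Nrf2 targets were lower in the APM library for 20 of 20 members, with a median of -0.39 (-0.42 to -0.37). Sqstm1, an autophagy receptor, was at 364.7 against 689.5 CPM, 1.89-fold lower (1.82 to 1.96), Slc7a11 1.89-fold lower (1.79 to 1.99) and Hmox1 1.72-fold lower (1.69 to 1.76). Without the genes that lead a cluster, these 3 among them, the median was -0.37. Nrf2 targets lead clusters 2 and 3, of which cluster 3 held 906 of the control but 179 of the APM cells and cluster 2 went the other way, 566 and 631. With cluster shares made equal the median was -0.05, and the log2 ratio of Slc7a11 was -0.17 and that of Sqstm1 -0.56. Metal response genes had 8 of 9 lower, 1 higher and a median of -0.59, or -0.26 with a pseudocount of 50 CPM and -0.22 with equal cluster shares. They included Mt2, a leading gene of cluster 2, at 1.90-fold lower (1.87 to 1.93), the iron exporter Slc40a1 at 1.98-fold and the phagosomal metal transporter Slc11a1 at 2.47-fold (2.08 to 2.94). Lysosomal genes had 18 of 24 lower, 5 higher and a median of -0.25, or -0.10 with equal cluster shares, with the cathepsins Ctsb 1.58-fold (1.55 to 1.62) and Ctsd 1.44-fold lower (1.43 to 1.46). MHC class II and class I lists had medians of -0.21 and -0.15, with 6 of 10 and 6 of 11 members lower, and class II had -0.02 with all alveolar macrophages as 1 class. Mitochondrial transcripts moved with these lists, 11 of 13 lower at a median of -0.30.

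Cell cycle genes were higher in the same clusters of the APM library, 17 of 22 with 0 lower and a median of 0.30 (0.25 to 0.35), or 0.16 as the mean over cells and -0.01 with cluster shares made equal. Ccnb2, a mitotic cyclin, was at 25.6 against 12.3 CPM, 2.07-fold higher (1.71 to 2.52), and Stmn1, a microtubule regulator, 1.62-fold higher (1.54 to 1.72). Alveolar macrophage markers had 15 of 17 higher, among them the fatty acid binding protein Fabp1 at 1.99-fold (1.91 to 2.08) and Car4 at 1.49-fold. Ccl6, a chemokine, was 1.94-fold higher (1.91 to 1.97) while its list was split, 5 higher and 3 lower of 16. Alternative activation had a median of 0.15, or 0.06 with no minimum of UMIs and -0.05 with equal cluster shares, with 9 of 13 higher, and the interferon list had 6 of 18 lower, 0 higher and a median of -0.03, or 0.17 with equal cluster shares. Markers of monocyte-derived macrophages were split, 4 higher and 5 lower of 14 at a median of 0.03, with Ms4a7 2.55-fold lower (2.22 to 2.93), a log2 ratio that was -0.32 with equal cluster shares. With all alveolar macrophages as 1 class that list had 9 of 15 higher, 4 lower and a median of 0.27. Macrophage clusters 1, 2, 3 and 5 held most of the control cells and clusters 4, 6, 2 and 5 most of the APM cells. Fabp1 leads clusters 4 and 6, which held 1029 and 688 APM cells against 21 and 42 control cells. Ccl6 leads clusters 4 and 5, Car4 cluster 5, Ccnb2 the proliferating cluster 10 and Stmn1 clusters 7 and 10, so these values combine cluster shares with expression.

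Transcripts of other cell types were higher in the APM macrophages. Hba-a1 was at 1238 against 52.0 CPM, 23.8-fold higher (22.1 to 25.6), Hbb-bs 20.3-fold (19.4 to 21.2), Hba-a2 20.2-fold (18.7 to 21.9) and Hbb-bt 17.2-fold (15.2 to 19.5). These haemoglobin genes mark red blood cells, and with equal cluster shares the log2 ratio of Hba-a1 was 2.83 and that of Scgb1a1 2.35. The club cell secretory genes Scgb1a1 and Scgb3a1 were 6.79-fold (6.51 to 7.09) and 7.31-fold (6.63 to 8.07) higher, and 10 of 10 epithelial markers were higher. The type named epithelial, which mixes epithelial and red blood cells by its leading genes, was 2.21% of the APM library (1.77 to 2.72) and 0.281% of control (0.140 to 0.502). Its 86 APM cells held haemoglobin at 402700 CPM, and own clustering set apart 26 red blood cells, 92.3% of them from this type.

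In Macrophage 8, with 205 APM and 107 control cells, fewer lists stood apart. MHC class II genes had 6 of 8 higher, 0 lower and a median of 0.35, with H2-DMa 1.60-fold (1.13 to 2.32) and Cd74 1.34-fold higher (1.24 to 1.44). The median was -0.02 when all alveolar macrophages were 1 class. Heat shock and immediate early genes had 6 of 17 lower, 0 higher and a median of -0.45 (-0.67 to -0.09), among them Jun at 5.01-fold (2.22 to 12.4) and Hspa1a at 2.80-fold lower (2.23 to 3.52). That median was 0.02 in the single class. Nrf2 targets had a median of 0.00 with 4 of 18 lower and 1 higher, alternative activation a median of -0.11 against a mean of 0.13, and the interferon list was not measured. Gm26917 was 18.1-fold lower (13.7 to 24.4) and Gadd45g, a stress response gene, 3.88-fold lower (2.17 to 7.17). Hba-a1 was 62.4-fold (36.4 to 117), Hba-a2 59.6-fold (32.3 to 125) and Hbb-bs 47.7-fold higher (33.1 to 71.3), and Ccl5 28.3-fold higher (4.88 to 1137) on 1 control UMI, a gene that dendritic cells of the APM library held at 6754 CPM and T cells at 3835 CPM.

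HDM+APM was compared with HDM to ask what earlier dust exposure added to the allergen response. In Macrophage 8, with 109 HDM+APM and 139 HDM cells, chemokines were lower in the combined exposure, 13 of 17 with 1 higher and a median of -1.23 (-1.48 to -0.78). The median was -0.56 as the mean over cells, -0.65 with no minimum of UMIs, -0.66 with a pseudocount of 50 CPM and -0.77 over members with at least 100 UMIs. Cxcl3 was at 12.2 against 124 CPM, 10.2-fold lower (4.41 to 29.0), Ccl12, a monocyte attractant, 6.29-fold lower (2.80 to 16.6) and Ccl5 4.12-fold lower (2.74 to 6.38). T cells, which lead in Ccl5, were 49.6% of the HDM and 12.1% of the HDM+APM library. Pro-inflammatory mediators had 4 of 5 lower, 0 higher and a median of -0.84, or -0.24 with no minimum of UMIs, with Il1b 2.303-fold (1.58 to 3.41) and Tnfaip3, an inhibitor of NF-kB, 3.13-fold lower (1.59 to 6.63). Granulocyte-like cells, 13.3% of HDM and 3.47% of HDM+APM cells, held Il1b at 1139 CPM in the HDM library against 196 CPM in Macrophage 8, and T cells held Tnfaip3 at 147 against 76.2 CPM. MHC class I genes had a median of -0.25 with 4 of 11 lower, among them H2-K1 at 1.48-fold (1.37 to 1.61). Fbp1, of gluconeogenesis, was 7.69-fold lower (4.28 to 15.0), and the collagenase Mmp13 15.0-fold lower (3.79 to 130) on 2 UMIs.

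Higher in Macrophage 8 of the HDM+APM library were Retnla, at 3653 against 213 CPM or 17.1-fold (14.0 to 21.2), and Lyz1, a lysozyme, at 223 CPM against 0 UMIs, at least 34.1-fold. The acute phase gene Saa3 was at least 21.4-fold higher, the matrix protein Ecm1 11.5-fold (5.62 to 27.4), the transcription factor Klf2 8.02-fold (4.503 to 15.5) and the complement component C4b 13.3-fold (4.91 to 50.3). Retnla, Saa3 and C4b are leading genes of the cells named classical monocyte, which only the HDM+APM library held. T cells of that library held Retnla at 1100.1, Saa3 at 88.8 and C4b at 85.4 CPM, beside 3653, 139.8 and 115.5 CPM in Macrophage 8. Retnla was highest in the type named epithelial, at 75233 CPM on 3838 UMIs in 26 cells. The cells named classical monocyte also held Ecm1 and Klf2, at 1359 and 1276 CPM, and B cells Klf2 at 919 CPM. Classical monocyte genes had 7 of 11 higher and 1 lower, with Plac8 2.93-fold higher (2.05 to 4.27) and Ly6c2 3.94-fold lower (1.85 to 9.36). B cells, which held Plac8 at 2612 CPM, made up more of the HDM+APM library, and T cells, which held Ly6c2 at 560.3 CPM, less of it. The interferon list had 4 of 16 higher, 0 lower and a median of 0.20 (0.02 to 0.47), which was -0.02 in cells thinned to 1000 UMIs. Alternative activation was split, 5 higher and 8 lower of 21 at a median of -0.07, or 0.00 with TMM scaling, and Nrf2 targets were split at 3 higher and 2 lower of 18. Haemoglobin went the other way: Hba-a1 was at 8.10 against 1809 CPM, 223-fold lower (86.9 to 821), Hbb-bs 126-fold (68.4 to 264) and Hba-a2 117-fold lower (53.4 to 320). Scgb1a1 was 4.72-fold higher (3.91 to 5.73), with 5 of 7 epithelial markers higher.

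T cells of the HDM+APM library, 136 against 493 in HDM, held less of the regulatory T cell list, with 5 of 10 members lower, 1 higher and a median of -0.74 (-0.96 to -0.35), or -0.45 with a pseudocount of 50 CPM. Foxp3, the lineage factor of regulatory T cells, was 4.25-fold lower (1.33 to 21.7) on 3 UMIs, Il2ra 3.48-fold lower (1.07 to 17.9) on 3 UMIs and Ikzf2, which encodes Helios, at 129.8 against 249.6 CPM, 1.92-fold lower (1.35 to 2.80). The chemokines Ccl4 and Ccl3 were 22.0-fold (10.0 to 60.5) and at least 7.47-fold lower. Both lead the granulocyte-like cells, at 27549 and 6882 CPM in the HDM library against 452 and 76.6 CPM in T cells, and that type was 13.3% of HDM and 3.47% of HDM+APM cells. T helper 2 genes had 2 of 5 higher and 1 lower, with Gata3 1.77-fold higher (1.16 to 2.67), and T helper 1 and 17 genes had 0 of 5 higher or lower. The medians of these 2 lists, 0.14 and 0.10, had negative means beside them, and the second was -0.29 in cells thinned to 1000 UMIs. Interferon genes had 7 of 18 higher, 0 lower and a median of 0.31 (0.12 to 0.47), with Cxcl10 13.2-fold (6.62 to 29.2) and Rsad2 2.22-fold higher (1.38 to 3.55), both highest in granulocyte-like cells, at 1797 and 2966 CPM. Transcripts of macrophages and epithelium moved with these: Retnla was 13.4-fold (10.2 to 17.9), Fn1 16.4-fold (8.86 to 33.1) and Slpi 13.2-fold higher (7.01 to 26.8), and 4 of 7 monocyte-derived macrophage markers were higher. Hbb-bs was 37.2-fold lower (20.1 to 77.8).

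HDM+APM was compared with APM to ask how cells differed with the allergen in dust-exposed lungs. Macrophage 8 was 5.5% of APM and 70.3% of HDM+APM alveolar macrophages, with median depths of 1182 and 4849 UMIs. Ratios within it may again reflect different cells as well as changed expression. In Macrophage 8 alternative activation genes were higher, 13 of 18 with 0 lower and a median of 1.499 (1.14 to 2.13). Retnla was at 3653 against 10.4 CPM, 350.5-fold higher (120 to 1701) on 3 APM UMIs, and Ccl8 53.7-fold higher (9.39 to 2142) on 1. Retnla was also at 1100.1 CPM in T cells of the HDM+APM library, against 0 UMIs in APM, at 16611 CPM in the cells named classical monocyte and at 75233 CPM in the type named epithelial, its highest level there. With 5% free RNA subtracted its log2 ratio in Macrophage 8 went from 7.49 to 7.38. Under that step its log2 ratio in T cells was still 6.33. The step therefore leaves Retnla in T cells and cannot decide whether free RNA plays a part. Interferon genes had 12 of 14 higher, 0 lower and a median of 2.03 (1.63 to 2.40). Isg15, a ubiquitin-like antiviral protein, was 19.2-fold higher (6.40 to 94.9) on 3 APM UMIs, Irf7, a regulator of the response, 26.2-fold (4.48 to 1059) on 1, and Cxcl10 at least 5.64-fold. Granulocyte-like cells of the HDM+APM library held these 3 at 3308, 884 and 1797 CPM. Chemokines had 7 of 12 higher, 1 lower and a median of 1.20, and MHC class I 6 of 10 higher, 0 lower and a median of 0.53, with B2m 2.11-fold higher (1.93 to 2.32). Plac8 was at least 25.1-fold and Saa3 at least 13.4-fold higher. Other types of the HDM+APM library held them too, Plac8 at 2612 CPM in B cells and 625 CPM in T cells, and Saa3 at 88.8 CPM in T cells against 139.8 CPM in Macrophage 8. With a pseudocount of 50 CPM the alternative activation median was 0.81 and the interferon median 1.14, and chemokines had 1.89 as the mean over cells. Unfolded protein response genes had 7 of 11 higher, 0 lower, and complement genes 5 of 10 higher, 2 lower.

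Nrf2 targets were again lower in the allergen library, 14 of 18 with 0 higher and a median of -0.97 (-1.30 to -0.87). Hmox1 was at 249 against 1536 CPM, 6.16-fold lower (5.04 to 7.59), Slc7a11 3.50-fold (2.09 to 6.05) and the peroxidase Prdx1 3.35-fold lower (3.03 to 3.70). Hspa1a was 16.4-fold lower (9.45 to 30.8) and Fabp1, an alveolar macrophage marker, 12.9-fold lower (5.47 to 36.9). T cells held less Prdx1 too, at 1198 CPM in APM and 311 CPM in HDM+APM. All cells named alveolar macrophage, which held Prdx1 at 4776 CPM in APM, were 95.04% of APM and 13.8% of HDM+APM cells. What their free RNA adds to Macrophage 8 was not tested. Hbb-bs was at 20.3 against 9846 CPM, 486-fold lower (264 to 1014), Hba-a1 712-fold lower (278 to 2618), and 5 of 7 epithelial markers were lower. Mitochondrial transcripts had a median of 0.63, with 9 of 12 higher. Macrophages 1 to 7, 9 and 10 numbered 46 in the HDM+APM library and were not compared.

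T cells of the HDM+APM library, 136 against 52 in APM, carried more interferon response transcripts, 11 of 15 with 0 lower and a median of 2.26 (1.84 to 3.45), or 1.70 with 5 members at 0 UMIs set to their bound and 1.44 with a pseudocount of 50 CPM. Ifi27l2a, an interferon-induced gene, was at 1756 against 63.9 CPM, 27.5-fold higher (10.7 to 101), Ifit1 at least 4.56-fold and Cxcl10 at least 3.63-fold higher. Granulocyte-like cells held the last 2 at 1740 and 1797 CPM. Cd8a and Cd4, the coreceptors of the main T cell subsets, were at 109 and 71.7 CPM against 0 UMIs in APM, at least 2.28-fold and 1.497-fold higher. Plac8 was 19.6-fold higher (5.34 to 163) on 2 APM UMIs, and B cells, which hold it at 2612 CPM, numbered 449 in HDM+APM and 3 in APM. Nrf2 targets had 5 of 8 lower, 0 higher and a median of -1.28, with Prdx1 3.85-fold lower (2.80 to 5.29), and Mt1 was 18.5-fold lower (11.7 to 30.3). Alveolar macrophages, 95.04% of APM and 13.8% of HDM+APM cells, held Prdx1 at 4776, Mt1 at 9780 and Cd9 at 3246 CPM in the APM library. Cd9, a membrane organiser, was 5.69-fold (3.16 to 10.4) and Lmo4, a transcriptional cofactor, 4.53-fold lower (2.67 to 7.67). Retnla was at least 22.95-fold higher, and Hbb-bs 127-fold (68.1 to 268) and Hba-a1 106-fold lower (52.6 to 249).

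Aryl hydrocarbon receptor targets had under 5 measured members in every macrophage comparison and were not measured. In GENCODE vM21 on mm10, Hmox1 lies on chromosome 8 at 75093621 to 75100589, Slc7a11 on chromosome 3 at 49892526 to 50443614, Retnla on chromosome 16 at 48842551 to 48844461, Isg15 on chromosome 4 at 156199424 to 156200818 and Ccl17 on chromosome 8 at 94810453 to 94812036. Mmp12 lies on chromosome 9 at 7344381 to 7369499, Hba-a1 on chromosome 11 at 32283511 to 32284465 and Hbb-bs on chromosome 7 at 103826534 to 103828096. All are protein-coding genes.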

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

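The test of macrophages as the only source of haemoglobin was chosen after its values had been seen, and the other 2 tests in this part before. Of 3374 genes of Macrophage 8 with at least 50 CPM in a library and 50 UMIs over the 4, 7 had both an HDM effect and an APM effect that turned with the other exposure. Each of the 4 ratios had an interval off 1 and a log2 of at least 1 either way, and 31 genes were named for this class, these 7 among them. With 1 library per group, the differences were not tested.

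Of these genes 4 encode haemoglobin, which red blood cells make. For Hba-a1 the log2 ratio of HDM was 4.15 without APM and -8.32 with it, that of APM was 5.82 without HDM and -6.65 with it, and the difference was 12.5 either way. Hbb-bs had 3.57 and -8.35 for HDM, 5.51 and -6.41 for APM, and a difference of 11.9. Hba-a2 had 4.14 and -7.59, 5.71 and -6.01, and a difference of 11.7. Hbb-bt had 4.59 and -7.07, 6.56 and -5.10, and a difference of 11.7. Ccl5, a T cell chemokine, had 3.93 and -1.58 for HDM, 3.63 and -1.88 for APM, and a difference of 5.51. The lysozyme gene Lyz1 and the transcription factor Klf2 went the opposite way. Lyz1 had -2.58 and 3.78 for HDM, -1.82 and 4.54 for APM, and a difference of -6.36. Klf2 had -2.12 and 1.85, -1.35 and 2.63, and a difference of -3.97.

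Haemoglobin UMIs per alveolar macrophage were 0.965 in control, 16.99 in HDM, 16.5 in APM and 0.213 in HDM+APM. Macrophages captured together with a red blood cell would leave most of these UMIs in a small share of cells, but 70.7% of the APM macrophages were needed to hold 90% of them, and the top 1% held 35.4%, which argues against it as the whole source. Transcripts made or taken up by macrophages alone would be scarce in other types, yet in the APM library the lowest other type, dendritic cells, held 0.607 of the macrophages' 5562 haemoglobin CPM (0.537 to 0.684), granulocyte-like cells 1.02 and T cells 1.65, against medians of 0.157, 0.110 and 0.0869 for 16 alveolar macrophage markers, which argues against it. Free RNA in the droplets would give every cell type a similar number. The highest type had 3.89 times the UMIs per cell of the lowest in that library, between the limits of 3 and 10 set in advance. Whether free RNA is the whole source therefore stays open. The 3.89 is a ratio of means. The medians were 10 haemoglobin UMIs in macrophages and in dendritic cells, 5 in T cells and 4 in granulocyte-like cells. Of the APM macrophages 99.8% held at least 1 such UMI, and 100% of the other 3 types did. The types also differ in depth, and its part was not tested. The labels say that the lavage was done so as to avoid blood, and a difference between lavages may account for a pattern seen in 1 library per group.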

How the results depend on the processing

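All cells named alveolar macrophage taken as 1 class, and shares without the cells named classical monocyte and B cells 2, were chosen after seeing the data, as were leaving haemoglobin out of the total, leaving genes that lead a cluster of the class out of the lists and making cluster shares equal. The 5 lists treated as main results in macrophages (alternative activation, chemokines, Nrf2, interferon, MHC class I) were picked from the fixed lists after their medians were known. No paired analysis was possible because each group is 1 pooled library. Removal of doublets was not run, since the caller did not work, and other Leiden resolutions do not apply to deposited types. A change of setting reversed 2 and moved 217 of 852 recomputed gene ratios, reversed 15 and moved 178 of 1246 list medians, and moved 32 of 108 shares past their interval. The rest stayed within their interval, although 51 of these list medians, and 24 of the moved ones, had an interval that took in 0 and changed sign. Depth limits T cells of the APM library, with 62584 UMIs in 52 cells, and Macrophage 8 of the control library, with 140468 UMIs in 107 cells. TMM scaling shifted the median of all genes to 0.21 in Macrophage 8 for HDM over control, to 0.12 for APM over control and for HDM+APM over APM, and to 0.35 in T cells for HDM+APM over APM, where it was -0.12 without. Thinning shifted it to -0.15 in Macrophages 1 to 7, 9 and 10, called the other clusters below, for HDM over control. Unless said otherwise the values that follow are median log2 ratios, and the cause was not tested.

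With TMM factors, Macrophage 8 had Nrf2 at -1.02 for HDM over control, 0.12 for APM over control and -0.82 for HDM+APM over APM, and alternative activation at 0.0017 (reversed) for HDM+APM over HDM. Lysosomal genes of the other clusters for HDM over control went from 0.13 to -0.055. Without genes that lead a cluster of the class, Macrophage 8 had alternative activation at 1.08 for HDM over control, and Nrf2 of the other clusters was -0.64 for HDM and -0.37 for APM over control. With cluster shares made equal, APM over control in the other clusters had Nrf2 at -0.051 and chemokines at 0.089, and reversed to -0.053 for alternative activation, 0.17 for interferon and -0.0080 for cell cycle. The Nrf2 and cell cycle medians thus shrank most of the way to 0, while chemokines and interferon, near 0 before, moved away from it. This step left out cluster 10, with 39 APM and 9 control cells, but without it and with shares as they are Nrf2 and cell cycle still had -0.39 and 0.295. Clusters are themselves drawn from expression, and cluster 4 had 21 control cells. It could not be done for HDM over control, where each cluster held under 20 HDM cells.

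With all cells named alveolar macrophage as 1 class, the Macrophage 8 results for HDM over control became 2.54 for chemokines and 1.29 for interferon, and reversed to 0.10 for cell cycle, 0.23 for heat shock and 0.68 for Gm26917. For APM over control they became -0.044 for chemokines, -0.39 for Nrf2 and -0.13 for MHC class I, and reversed to -0.022 for MHC class II, 0.024 for heat shock and 0.094 for Unc119, which was -1.06. Nrf2 was 0.18 for HDM+APM over HDM. For HDM+APM over APM, Nrf2 was -0.76, MHC class I 0.96 and cell cycle, at -0.43 before, 0.10. Against the other clusters for HDM over control, that class gave 2.06 for alternative activation, 2.54 for chemokines, -1.21 for Nrf2 and 1.29 for interferon. Macrophage 8 was 2.76% of that class in control and 69.8% in HDM, so its values combine cluster shares with expression.

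In cells thinned to 1000 UMIs, which left out 41 control, 18 HDM, 73 APM and 24 HDM+APM cells of Macrophage 8, HDM over control gave 2.67 for alternative activation, 3.03 for chemokines and 2.66 for interferon. HDM+APM over HDM gave -1.59 for chemokines and reversed interferon to -0.016. In the other clusters HDM over control reversed to -0.017 for chemokines, -0.0086 for interferon and -0.29 for complement, and T cell interferon for HDM+APM over APM was 3.63.

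With the mean over cells, Macrophage 8 gave 2.202 for alternative activation, 2.90 for chemokines and -1.53 for Nrf2 in HDM over control, and 0.94 for chemokines in APM over control. HDM+APM over HDM gave -0.56 for chemokines and reversed MHC class II to -0.024, and HDM+APM over APM gave 1.89 for chemokines, -1.35 for Nrf2 and 2.44 for interferon. Nrf2 in the other clusters was -0.63 for HDM and -0.36 for APM over control.

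With members of at least 100 UMIs, Macrophage 8 gave 2.28 for alternative activation and 2.69 for chemokines in HDM over control, -0.77 for chemokines in HDM+APM over HDM and 2.36 for alternative activation in HDM+APM over APM. With no minimum these were 1.39, 1.08 and -0.65 for the first 3, interferon was 1.42 in HDM over control and chemokines 0.83 in HDM+APM over APM. Alternative activation of the other clusters in APM over control was then 0.056.

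With a pseudocount of 1 CPM, Macrophage 8 interferon was 2.90 in HDM over control, chemokines -1.54 in HDM+APM over HDM, and alternative activation 2.13 and interferon 2.63 in HDM+APM over APM. The other clusters had 1.63 for alternative activation and 1.24 for interferon in HDM over control, and -0.079 for chemokines in APM over control. With 50 CPM, Macrophage 8 in HDM over control had 1.35 for alternative activation, 1.59 for chemokines, 1.09 for interferon and 0.71 for MHC class I, and chemokines were -0.66 in HDM+APM over HDM. HDM+APM over APM had 0.81 for alternative activation, 0.87 for chemokines, -0.82 for Nrf2 and 1.14 for interferon. The other clusters had 0.64, -0.61, 0.40 and 0.53 for alternative activation, Nrf2, interferon and MHC class I in HDM over control, and -0.36 for Nrf2 and -0.090 for MHC class I in APM over control. T cell interferon in HDM+APM over APM was 1.44.

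Of the shares of cells that moved, those treated as main results are given here. In all, 10 moved with the limit of 1000 UMIs and 10 with that of 500 genes. Own clustering moved 5, and leaving out the cells named classical monocyte and B cells 2 moved 7. Over cells of at least 1000 UMIs, alveolar macrophages were 25.8% in HDM and 97.1% in APM, B cells 16.1% and granulocyte-like cells 0.285% in HDM. Over cells of at least 500 genes they were 25.8 and 97.3%, granulocyte-like cells 1.30% and T cells 54.3% in HDM. Own clustering left several macrophage clusters unnamed. A cluster of 409 cells led by Mmp12, Ccl24 and Ccl17 was named monocyte-derived or interstitial macrophage, although 97.6% of it was alveolar macrophage in the deposited annotation. Alveolar macrophages were then 48.0% in control, 3.52% in HDM, 66.5% in APM and 0.623% in HDM+APM. Monocytes were 0% in HDM+APM. The cells named classical monocyte made up 97.5% of a cluster of 315 cells that was also named monocyte-derived or interstitial macrophage. Without the cells named classical monocyte and B cells 2, HDM+APM held 37.7% alveolar macrophages, 33.1% T cells, 10.9% B cells and 0% classical monocytes.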

Other observations

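The count of monocyte markers and the comparison with doublets were chosen only after the cells concerned had been looked at, and the other tests in this part were set before their results were seen.

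Across whole lavages, where cell composition and expression act together, markers of several cell types moved with the allergen. Mature dendritic cell markers, of cells leaving for lymph nodes, were higher in HDM than in control for 8 of 8 members, with a median log2 ratio of 2.00, and markers of type 2 innate lymphoid cells for 5 of 6, with a median of 2.05. The innate lymphoid list holds Arg1, which leads Macrophage 8, and Gata3, which is also in the T helper 2 list. T cells were 0.332% of control and 49.6% of HDM cells, and no deposited type was named innate lymphoid. The rise of that list therefore cannot be assigned to innate lymphoid cells. Neutrophil markers had 9 of 10 higher at 1.96. Against HDM alone, the HDM+APM lavage had mature dendritic markers lower for 6 of 8 with a median of -1.60, neutrophil markers lower for 9 of 10 at -1.31 and regulatory T cell genes lower for 9 of 10 at -1.40. Complement genes went up instead, 9 of 12 higher and 2 lower at 2.22. In HDM+APM, B cells 2 alone held 2297729 of the 5197132 UMIs, and 308 cells were those named classical monocyte. HDM held 9 and 0 cells of these types, so their UMIs lower the CPM of every other type in HDM+APM. The falls above cannot be told apart from that effect. The complement genes C1qb, C1qc and C4b lead the cells named classical monocyte. Lipid and surfactant handling genes, a main task of alveolar macrophages, were lower in HDM than in control for 19 of 23 with 3 higher, at -0.86, and in HDM+APM than in APM for 18 of 23 with 4 higher, at -1.14.

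The cells named classical monocyte were weighed first. Only 3 of the 14 fixed monocyte markers were highest in them, which argues against classical monocytes as named. All 12 of 12 cavity macrophage genes not looked at before were highest in them with the other types taken over the 4 libraries (Hgf within counting error of alveolar macrophages, and Car6 under the granulocyte-like cells' 1 UMI within the HDM+APM library), which is consistent with macrophages of the pleural or peritoneal cavity as a hypothesis. Doublets of 2 other cell types only mix what both hold. A first test of this gave no decision. In it 5 of the 12 cavity genes stood above alveolar macrophages, T cells, B cells, granulocyte-like and epithelial cells of the HDM+APM library, by uncorrected intervals. Against alveolar macrophages, T cells and B cells alone, 11 did. In the test that replaced it, 8 genes (Fn1, Alox15, C1qb, C1qc, Cd5l, Prg4, Pf4 and Slpi) stood above 2 times each of 16 other clusters. Its intervals were corrected for 13838 genes and 16 clusters, and it argues against doublets as the whole source. Whether cells named classical monocyte entered the airspaces in the combined exposure or came into 1 pool with fluid from outside the lung stays open. In the other cells of the HDM+APM library Prg4 was at 54.3 CPM and Saa3 at 82.4 CPM against 1.04 and 0.521 CPM in HDM.

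B cells 2, with 404 of its cells in HDM+APM, was compared with the 45 cells of B cells 1 in the same library, so that library differences play no part. Genes of B-1 cells, a B cell type of the body cavities, had a median log2 ratio of 1.21 over 7 measured members. That lay at percentile 99.94 of matched random lists. After thinning to 1000 UMIs the median was 1.24. B cells 2 was the deeper cluster (median 5447.5 against 1796 UMIs). Thinning leaves the expected proportions of a summed cluster unchanged, so it cannot decide whether that depth plays a part. The ratio's own interval excluded 1 for 2 of the 7, and with 3 members at 0 UMIs in B cells 1 set to their bound the median was 0.47, below the 0.5 set in advance, so the result rests on few counts. Of 9 B-1 genes whose values had been seen earlier, 4 had an interval above 1 at a list median of 0.44, with Siglecg, Bhlhe41 and Vim near a ratio of 1, S100a6 was 3.19-fold higher (2.67 to 3.84) and Zcwpw1 18.1-fold (3.24 to 718), while the follicular B cell genes Ccr7 and Bach2 were 9.39-fold and 6.59-fold lower, although the follicular median of -0.50 lay at percentile 22.2. A candidate explanation is a B-1 population, which like the cavity macrophages may be recruited or carried over, and 1 library cannot separate these.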
